A study of Rattus norvegicus with 8 samples.

How the data were processed

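Gene expression was measured on 2-colour Agilent oligonucleotide microarrays in the dentate gyrus of ovariectomized adult female Sprague-Dawley rats. The dentate gyrus is the part of the hippocampus that holds the granule cells. Per the labels' protocols, the rats received estradiol benzoate (EB), an esterified form of the main ovarian estrogen, or the oil vehicle alone, 1 week after the ovaries were removed. There were 4 EB samples and 4 oil samples, which the submitters call biological replicates. The labels place the 8 samples on 4 arrays of 1 slide, with 2 samples of the same group on each array, 1 labelled with Cy3 and 1 with Cy5. Oil replicates 1 and 2 shared array 1, oil replicates 3 and 4 array 2, EB replicates 1 and 2 array 3, and EB replicates 3 and 4 array 4. Odd-numbered replicates carried Cy3 and even-numbered replicates Cy5, so dye was balanced between the groups and array was nested within them.

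The deposited table holds log2 values, with 1 column per sample and 1 row per array feature. The scanner images were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. How background was treated and which rule left an entry without a value are not given in the sources used here. The scale was worked out from the deposited log2 values. When each value was taken as a power of 2 and multiplied by a constant found for its column, every value in every column came out as a whole number (tolerance 0.002, widened in proportion for bright features). The median of each deposited column was 0. The values are therefore log2 ratios of a whole-number intensity to the median intensity of the same column, and are not centred per feature. Of the 45018 features in the table, 15055 had no value in any sample and 17975 had a value in all 8. Entries without a value were treated as missing. Features that had a value in the 7 other samples but not in a given sample were mostly dim, with a median log2 value in those others between -2.32 and -1.18.

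The rows carry feature numbers only. No table used here pairs these numbers with probes or genes, so no feature is named as a gene, and repeated spots of a probe could not be averaged. The 36 gene lists and the report on neuropeptide Y (Npy), which the series title names, were fixed before the data were examined and could not be applied. Their alternatives were not run either. Npy is not analysed here for that reason. Correlations between features across the 4 samples of a group were not computed, because 4 samples are too few.

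The 20804 features with at least 3 values in each group were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior). Treatment and dye were fixed terms and array was a random block fitted with duplicateCorrelation. The moderated test was two-sided, with Benjamini-Hochberg adjustment over all tested features, and a feature was called at an adjusted p under 0.05. The deposited normalization was kept because all 8 column medians were equal, a rule set before the data were examined. Over the 20804 tested features alone the column medians were not equal, and ranged from 0.30 in EB replicate 2 to 1.00 in EB replicate 1. The features printed below were chosen by a rule set beforehand, the largest changes among called features whose samples all lay on the same side of the other group's mean. The rule allowed 12 in each direction. Because the features have no gene names, only the first 2 in each direction are printed.

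Feature numbers run to 45220. Among the divisors of that number from 20 to 400, 85 was the smallest for which the remainder of the feature number explained a large part of the variance of the difference between EB and oil, at 37.4%. Its multiples 170 and 340 explained 37.3% each, and no other explained over 0.3%. Features were therefore treated as lying in 532 rows of 85, and the place within a row is called the array column. This layout was inferred from the data. The position correction, chosen after the data were seen, subtracted from each sample the median deviation from the feature mean within blocks of 14 rows by 5 columns. There were 642 such blocks with a median of 33 tested features.

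The within-group spread was compared as the median over features with 8 values of log2 of the SD in EB over the SD in oil, after each feature's dye effect was removed. Its exact permutation test used all 35 splits of the group-centred samples. Counts and intensities per sample were compared with two-sided exact permutation tests. All these permutation tests treat the 8 samples as independent, although 2 samples of a group shared each array. The replicate numbers were not treated as pairing the samples, because the samples share only a number.

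The fit was tested on simulated data with the features and missing entries of the real comparison. Noise was independent between samples, with the spread of the position-corrected values, and no position pattern was present. Of 200 changed features, it recovered 38% of those changed 2-fold and 79% of those changed 4-fold, with 8 false calls among the rest. The block medians that position correction removes from the real samples were then added to these data. With them the same fit recovered 62% and 93%, with 1215 false calls. Noise shared by the samples of an array was not simulated, so the counts of false calls do not cover it. Alternatives changed the dye term, the array block, the replicate block, the averaging of samples on an array, the scaling, a filter on dim features, the prior, the sample weights, the threshold and the samples included. The number of arrays limits the precision, and arrays of the same group shared no samples with the other group. The pseudocount alternative did not apply, because the deposited values were already on a log scale.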

Results

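The data comprised log2 expression values from the dentate gyrus of ovariectomized rats, 4 given estradiol benzoate (EB) and 4 given oil. Between 22007 and 26742 of the 45018 features had a value in each sample. The median intensity of those features, recovered from the table, was lower in every Cy5 sample than in every Cy3 sample. It ranged from 733 to 1082.5 in the 4 Cy3 samples and from 333 to 515 in the 4 Cy5 samples. Pooled over the dyes, the number of features with a value did not differ detectably, with 24264 ± 2405 in EB and 24169 ± 1374 in oil (SD, n = 4 each, two-sided exact permutation p = 0.97). The median intensity was 650 ± 372 in EB and 620 ± 188 in oil (SD, n = 4 each, two-sided exact permutation p = 0.89). Within the dyes the differences ran in opposite directions, without overlap of the samples. Among Cy3 samples the mean number of features with a value was 26320.5 in EB and 23384 in oil, and among Cy5 samples 22208 in EB and 24953.5 in oil. The mean of the median intensities was 961 in EB and 776 in oil among Cy3 samples, and 339.5 in EB and 464.5 in oil among Cy5 samples. With 2 samples per group and dye, the smallest exact permutation p is 0.33. The pooled tests treat samples as independent, although 2 samples of a group shared each array. On all 4 arrays the Cy3 sample was brighter than the Cy5 sample. The ratio of the medians was 1.98 and 1.42 on the oil arrays and 3.13 and 2.52 on the EB arrays.

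**Figure D1:**
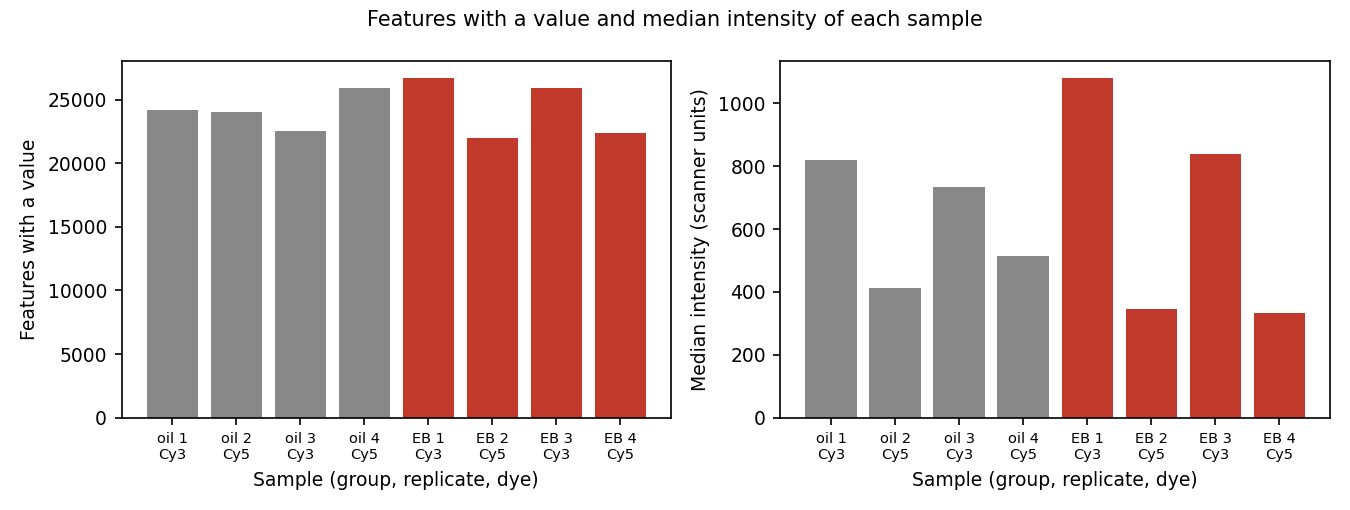
Bars show, for each of the 8 samples (oil grey, EB red), the number of features with a value (left) and the median intensity in scanner units (right). EB replicates 2 and 4, both Cy5, had the lowest median intensities, 346 and 333.

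Samples correlated closely over the tested features. Among the 7 samples other than EB replicate 4, pairwise Pearson correlations across features lay between 0.91 and 0.98, where features are not independent replicates. EB replicate 4 correlated less with the others, between 0.86 and 0.94. The SD of its deviations from the feature means was 0.83 log2 units, against 0.42 to 0.59 in the 7 other samples.

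The comparison of EB with oil asked which transcripts of the dentate gyrus differ after estrogen replacement. The files do not pair the features with genes, so features are given by number. In the fit with dye and array, 3163 of 20804 features passed an adjusted p under 0.05 (limma, Benjamini-Hochberg), 2763 higher and 400 lower in EB. The median size of the difference among them was 0.99 log2 units, with a median SE of 0.23. Of the called features, 2467 had every sample on the same side of the other group's mean, and 1500 differed by over 2-fold. At an unadjusted p under 0.05 there were 6922 features, where 1040 would be expected by chance if the p-values were well calibrated. Other splits of the 8 samples into 4 and 4 gave from 95 to 4069 such features. The 2 other splits that kept the samples of each array together gave 197 and 341. The figure of 1040 is therefore not a firm reference. After position on the array was corrected for in blocks, 4 features passed, all 4 higher in EB and all among the 3163. After that correction 4011 features had an unadjusted p under 0.05. Correction by array column instead also gave 4 calls, but 2 were higher and 2 lower in EB. Without position correction, the number of calls at an adjusted p under 0.05 was lower without EB replicate 1, at 3, and without EB replicate 3, at 1756. With the array block left out of the fit it was 564. The block had an estimated within-array correlation of -0.42. With 1 group per array, a negative correlation lowers the SE of the treatment difference for a given spread. With the 2 samples of each array averaged first, 2 arrays against 2, 0 features passed (limma, 5377 at an unadjusted p under 0.05).

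The difference between EB and oil followed position on the array. In array columns 1 to 35 the median difference was 0.53 log2 units over 8245 features, with 2486 called higher and 5 called lower. In columns 46 to 85 it was -0.17 over 10008 features, with 113 called higher and 375 called lower. Array column accounted for 37.0% of the variance of the difference across features, and array row for 3.2%. The difference of a feature correlated with that of the feature 85 numbers away at r = 0.39 and with that of the feature 42 numbers away at r = -0.31, across features. Within each sample, the median deviation in columns 1 to 35 minus that in columns 46 to 85 was 0.37 ± 0.06 log2 units in EB and -0.37 ± 0.07 in oil (SD, n = 4 each). It was above 0 in 4 of 4 EB samples and below 0 in 4 of 4 oil samples. Deviations were taken from the mean of both groups, so the EB and oil values mirror each other by construction. They cannot tell a gradient on the EB arrays alone or the oil arrays alone from opposite gradients on both. The array columns were inferred from the EB minus oil difference itself, so these values describe it and are not tested. Each array held 1 group only, so treatment could be set only against the spread between 2 arrays per group.

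**Figure D2:**
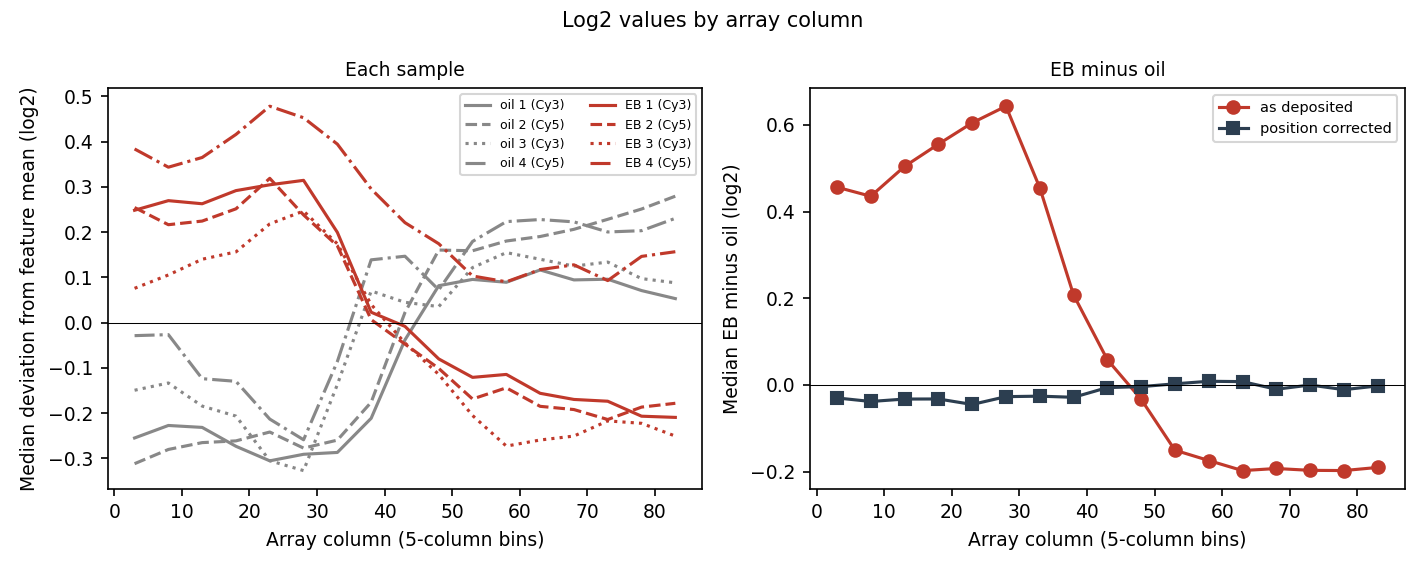
Left, the median deviation from the feature mean (log2) in 5-column bins of array columns, for each sample, with each sample first centred on its median. Right, the median EB minus oil difference (log2) in the same bins, as deposited and after position correction. The deposited difference ran from 0.64 in columns 26 to 30 to -0.20 in columns 61 to 65.

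**Figure D3:**
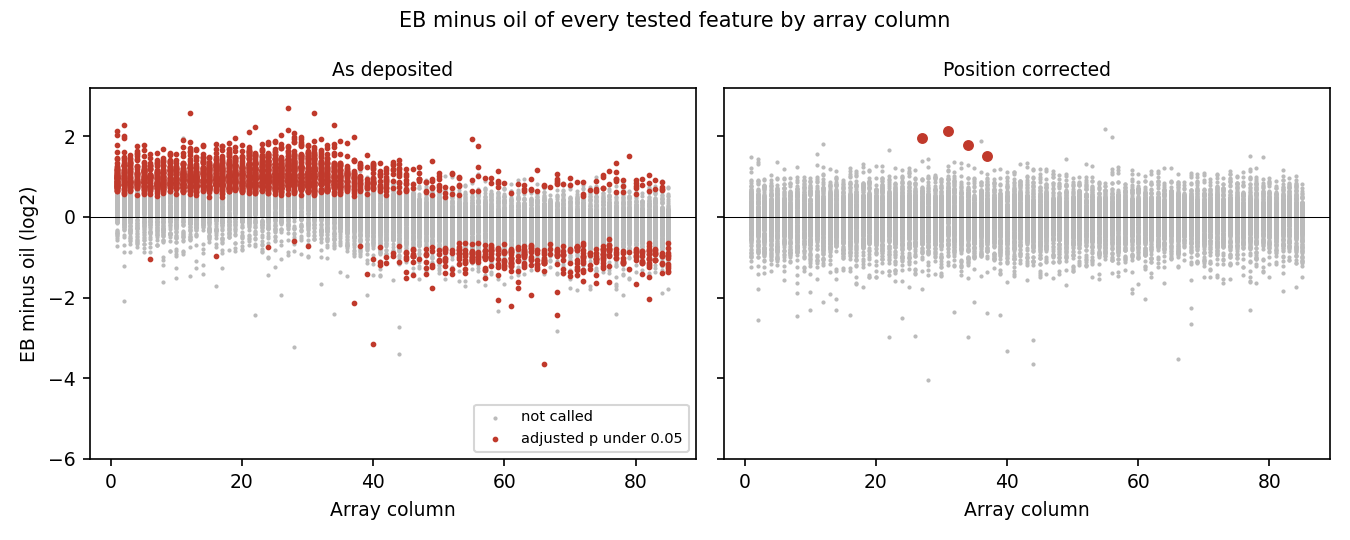
Each point is a tested feature, plotted by array column (x axis) and EB minus oil difference (log2, y axis), as deposited (left) and after position correction (right). Red points passed an adjusted p under 0.05, 3163 on the left and 4 on the right.

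Feature 42527, in array column 27, was 6.55-fold higher in EB. It was among the dimmest 25% of features, and its oil intensities of 65 to 111 scanner units were close to the lowest in the table (38 to 58 per sample), so the fold is uncertain. Its log2 value was -0.09 ± 0.46 in EB and -2.80 ± 0.74 in oil (SD, n = 4 each), with a log2 difference of 2.71 ± 0.21 (SE) and a limma adjusted p of 0.00043. Feature 21706, in array column 31, was 5.96-fold higher, with 2.71 ± 0.27 in EB and 0.14 ± 0.43 in oil (SD, n = 4 each). Its log2 difference was 2.58 ± 0.22 (SE, limma adjusted p = 0.00043). Both stayed past the threshold after position correction, at log2 differences of 1.95 ± 0.19 and 2.13 ± 0.16 (SE, limma adjusted p = 0.030 and 0.015). Feature 42527 also passed with correction by array column (limma adjusted p = 0.036). Some other position-corrected fits did not call it. Its limma adjusted p was 0.067 without the array block, 0.053 after quantile normalization and 0.19 without EB replicate 4. With the samples of each array averaged, neither feature passed after position correction. Over all alternatives run, the limma adjusted p ranged from 0.00037 to 0.31 for feature 42527 and from 0.00018 to 0.31 for feature 21706. Feature 44096, in column 66, had the largest negative difference under the naming rule, -3.65 ± 0.92 log2 units (SE, limma adjusted p = 0.023). Its values spread widely, with -0.90 ± 2.55 in EB and 2.75 ± 1.54 in oil (SD, n = 4 each). Its intensities in EB replicates 3 and 4, 67 and 134 scanner units, were also low, so the size of this difference is uncertain. Feature 21148, in column 68, was lower in EB by a log2 difference of -2.44 ± 0.44 (SE, limma adjusted p = 0.0055). Its values were -0.32 ± 1.38 in EB and 2.12 ± 0.51 in oil (SD, n = 4 each). The groups overlapped, with EB replicate 3 at 1.51 and oil replicate 3 at 1.48. Neither feature 44096 nor feature 21148 passed after position correction, at adjusted p = 0.22 and 0.17 (limma). Their log2 differences were still -3.53 ± 1.32 and -2.25 ± 0.62 (SE). Without EB replicate 1, 3 or 4 feature 44096 did not pass (limma adjusted p = 0.13, 0.057 and 0.069), and without EB replicate 1 feature 21148 did not (limma adjusted p = 0.099). With single samples left out, the log2 difference of feature 44096 ranged from -4.98 to -2.43. Over all alternatives run, that difference ranged from -6.34 to -1.12. It was -5.92 among Cy3 samples alone and -1.39 among Cy5 samples alone. Over all alternatives run, the limma adjusted p ranged from 0.0035 to 0.58 for feature 44096 and from 0.0025 to 0.36 for feature 21148.

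The calls were spread over all levels of brightness. In the dimmest 25% of features, 866 were called higher and 25 lower in EB. In the brightest 25%, 800 were called higher and 84 lower. The share of calls that were higher in EB depended on the scaling. It was 87.4% with the deposited scaling, 73.7% of 2173 calls when columns were centred on their medians over the tested features, and 65.3% of 1942 calls after quantile normalization. The median difference over all tested features was 0.09 log2 units with the deposited scaling and -0.06 after quantile normalization.

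The comparison was repeated within each dye, with 2 samples per group. Among Cy3 samples, 2014 features were called higher and 97 lower in EB. Among Cy5 samples, 132 were called higher and 1100 lower (limma, adjusted p under 0.05). The median difference was 0.40 log2 units within Cy3 and -0.16 within Cy5. These counts and their directions depended on the scaling. With columns centred on their medians over the tested features, 0 features passed within Cy3 (limma, 3559 at an unadjusted p under 0.05) and 0 within Cy5 (limma, 5064 at an unadjusted p under 0.05), and the median differences were -0.02 and 0.11. The differences measured in Cy3 and in Cy5 correlated across features at r = 0.31, and at r = 0.06 after position correction. Without position correction, it was 0.16 without EB replicate 1, 0.20 without oil replicate 1 and 0.42 without EB replicate 3. A test of the interaction between treatment and dye called 0 features (limma, adjusted p under 0.05), with 3506 at an unadjusted p under 0.05. In the fit with treatment and array, 744 features differed between the dyes (limma, adjusted p under 0.05).

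The spread of expression within a group did not differ detectably between EB and oil. The median SD over features was 0.40 log2 units in EB and 0.35 in oil, with n = 4 samples each. The median of log2 of the ratio was 0.14 (exact permutation p = 0.63 over 35 splits). With the dye effect not removed it was 0.56 (exact permutation p = 0.14). With the dye effect removed, leaving out oil replicate 1 or oil replicate 2 turned it to -0.05.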

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

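The tests of explanations in this part were all chosen only after the results had been seen.

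EB replicate 4 stood apart from the other 3 EB samples. The SD of its deviations from the feature means was 0.834 log2 units, and the gap to the nearest EB sample was 0.86 of the range of the group, above Dixon's 95% limit for 4 samples. This was 1 of 24 such tests, and chance flags about 1 in 20. A weak channel is argued against as the whole reason. In the brightest 25% of features its deviations had an SD of 0.82, against 0.44 in EB replicate 2, of similar median intensity. In the dimmest 25% the SD of EB replicate 4 was 0.60. EB replicate 4 lacked 1151 mostly dim features that all 7 other samples had, and EB replicate 2 lacked 677. Its SD in dim features leaves these out, so the contrast of bright with dim is less certain. Position on the array is argued against as the whole reason, because the SD was still 0.81 after position correction, against 0.53 at most in the other samples. No biological explanation was tested, and a difference of that animal, its dissection or its RNA remains open.

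A set of 16 features had a value in all 4 EB samples and in no oil sample, and 1 feature had the reverse. These features were outside the main test. They were dim, with a median log2 value of -2.61 in EB, and 6 of the 18 splits with balanced dyes gave as many in a direction, with up to 72.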

How the results depend on the processing

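The position corrections, the fits within 1 dye, centred or not, and the shuffled positions were chosen only after the results were seen. The number of called features (3163) depended heavily on the processing, and unless stated the cause was not tested. It was 564 without the array block, whose estimated within-array correlation was -0.42, and 0 with the 2 samples of each array averaged (limma, 5377 at an unadjusted p under 0.05), a fit with fewer samples. The number of calls was 1942 after quantile normalization, 1936 without the dimmest 50% of features (fewer features tested) and 4922 with sample weights. At other thresholds it was 5338 at an adjusted p under 0.10, 844 under 0.01, and 5724 at an unadjusted p under 0.05 with a fold over 1.5. Leaving out single samples gave 3 (EB replicate 1) to 4193 (oil replicate 1). There were 4 calls with position correction in blocks, all higher in EB, and 4 by array column, 2 higher and 2 lower. Quantile normalization and position correction gave 3 calls, 2 higher and 1 lower. The direction of these few calls thus depended on the correction. In blocks, there was 1 call without the array block and 2 without EB replicate 4. Shuffled positions gave 1418 calls and Cy5 samples alone 1232. With columns centred, 0 passed among Cy3 samples alone (limma, 3559 at an unadjusted p under 0.05) and 0 among Cy5 samples alone (limma, 5064). Position correction with the samples of each array averaged gave 0 (limma, 3123). The replicate block gave 3495 calls. The samples share only a number. Deviations of same-numbered samples correlated at 0.32, 0.50, -0.01 and 0.07 across features. In all, 3 of 8 samples correlated best with their own number, and 0 of 8 with the dye effect removed. Same-numbered samples always shared a dye, so the first figures include any dye effect, and removing it lowers their correlation by construction. These values therefore cannot tell whether the samples were paired. The spread ratio (0.14) stayed above 0 except without oil replicate 1 (-0.050) or 2 (-0.053), with a range of -0.053 to 0.415 over the samples left out and exact permutation p of 0.17 to 0.91. With the dye effect not removed it was 0.56 (exact permutation p = 0.14). The difference between array sides ranged from 0.70 to 0.78 with single samples left out. Group differences in features with a value (95.5) and in median intensity (30.1) turned sign with single samples left out, from -730 to 848 and from -114 to 136. Of the named features, 21706 kept its call in 25 of 29 alternatives, 42527 in 20 of 27, 21148 in 18 of 29 and 44096 in 12 of 29, and none changed direction. Npy, the gene lists and their alternatives were not run, nor was the pseudocount. Deposited intensities reached down to 38 scanner units, and background levels are unknown here, so dim features are the least certain.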

Other observations

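The tests of explanations in this part were chosen only after the results were seen, apart from quantile normalization, which was chosen before. The pattern is the 3163 features called between EB and oil. Of 34 splits of the 8 samples, 1, the real one, gave as many calls, with 3243 in these refits (within-array correlation from 4000 features) and 90 in the highest other, but 3 splits keep arrays whole, too few for a share under 0.05. Scaling of the columns is argued against as the whole reason, because quantile normalization gave 1942 calls. Position on the array is a candidate explanation: with the local median of each sample removed 4 calls were left, against 1418 with shuffled positions. The layout was inferred from the EB minus oil difference itself, and the shuffled positions do not allow for that choice. The median difference of the 3163 features fell from 0.99 to 0.45 log2 units and their median SE from 0.23 to 0.20, and of the 3159 calls that ended, 3063 had a smaller difference and 910 a larger SE, while 29 had neither.

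In simulated data with 200 changed features and the position pattern of the real samples added, position correction recovered 35% of the features changed 2-fold and 81% of those changed 4-fold, with 9 false calls. Without the correction the main fit made 1215 false calls on the same data. The added pattern was the block medians that the correction itself takes out, in the same blocks, so its removal was fixed in advance. Gradients within blocks, another layout or noise shared by the samples of an array were not simulated.

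An effect of EB at any position stays open, because 2 arrays per group give a weak test of treatment against differences between arrays. After position correction, the fit on the means of the arrays called 0 features (limma, 3123 at an unadjusted p under 0.05). In the fit on 8 samples, 3 of 34 splits of the corrected values, the real one included, gave as many features at an unadjusted p under 0.05. The count was 4162 in the real split and 5497 in the highest other. The others that gave as many, with 4382 and 5497, were not balanced in dye, unlike the real split. Among splits with balanced dyes the highest other gave 4067. The 2 other splits that kept arrays whole gave at most 542.

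For the 4 features called after position correction, which include features 42527 and 21706, 2 of 34 splits gave as many, with 1278 in the highest other, and again 3 splits keep arrays whole, too few for a share under 0.05. The split with 1278 set oil replicates 1 and 3 and EB replicates 1 and 4 against the rest. Unlike the real split it was not balanced in dye. Among splits with balanced dyes the highest other gave 1 call. The split with 1278 matched Cy3 against Cy5 except that EB replicates 3 and 4 were exchanged. With dye in the fit, it set EB replicate 3 against the other Cy3 samples and EB replicate 4 against the other Cy5 samples. EB replicate 4 had the widest deviations after position correction, with an SD of 0.81 against 0.53 at most in the other samples. What produced the high count was not tested. All 4 features lay in array columns 27 to 37, from the peak of the position profile into its fall. The median difference was 0.64 log2 units in columns 26 to 30 and 0.21 in columns 36 to 40. After correction it was -0.03 in each. Whether position contributed to these calls was not tested.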
